A study of Caenorhabditis elegans with 8 samples.

How the data were processed

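RNA was sequenced from whole nematodes of the N2 strain after feeding RNAi, in 8 libraries that the labels place in 3 groups: 2 fed the empty plasmid L4440, 3 fed an hlh-2 RNAi plasmid and 3 fed a lin-32 RNAi plasmid. Per the labels' protocols, total RNA was isolated with QIAzol and libraries were made with the TruSeq RNA v2 kit, which does not mark strand. Per the submitters' processing notes, the processing tools were bcl2fastq 1.8.4, TopHat2 2.1.0 and featureCounts 1.4.6-p4, with the genome build WBcel235. The annotation release behind the counts and the settings for strand, multi-mapping reads and overlapping genes are not given in the sources used here. The deposited table holds raw whole-number read counts per WormBase gene, 1 column per library. The values are whole numbers whose totals differ between libraries, as unnormalized counts do.

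The table has 46748 genes. Symbols came from a table of WormBase names, which matched 43693 IDs, and coordinates from the WBcel235 annotation of release 115, which held 46449 of them. Another 1755 IDs had counts and no symbol, and these took 0.855% to 0.940% of the counts of a library. Total counts ran from 22380739 in L4440 replicate 1 to 34814808 in the lin-32 RNAi library of replicate 2. Levels are given as CPM (counts scaled to a common library total). In the smallest library 1 CPM stands for 22.4 counts, so low genes carry wide counting error. Reads from ribosomal RNA genes took 0.399% to 1.29% of a library. Replicates of a group differed by far more than counting noise (chi-square per degree of freedom 5.58 to 16.0 over genes with at least 20 counts), so no library appears to be a second copy of another. The labels do not say whether replicates came from separate cultures, and p-values then measure the spread between these libraries, which may be technical.

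Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group, which left 14272, libraries were scaled by TMM, and all 8 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with the group as the only term. The 3 comparisons were tested as contrasts, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Adjusted p-values below are from this test unless another is named. Standard errors of log2 fold changes were taken from the F statistic. The common dispersion was 0.00270, a biological coefficient of variation of 5.19%. CPM values use the TMM-scaled library sizes and are given as mean ± SD.

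A total of 33 gene lists was fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for naming genes. Of the list names, 6 matched no symbol, and the mitochondrial genome list was taken by chromosome. Lists with at least 5 tested members were tested with camera on the same fit, with the preset correlation of 0.01 and adjustment over the lists within a comparison. The correlation estimated from the data and fry were run as alternatives. The fry p-value tests whether the members move one way on balance and does not compare them with other genes. Genes were named by a rule: among genes past the threshold whose libraries did not overlap between the compared groups, the 6 with the largest change and a mean of at least 5 CPM and the 6 with the smallest p and a symbol of letters and a number, in each direction. In a direction with fewer than 5 such genes all were to be named. The targeted genes are always named, as are up to 4 members of each list that passed and up to 2 of any other. A gene outside the rule is said to have been chosen after its values were seen.

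Both comparisons with L4440 share its 2 libraries, so their overlap was set beside 100 simulated data sets with no change, drawn without pairing of libraries. The covariance that pairing adds was estimated from deviations of log2 CPM, with edgeR's default prior count for fold changes, as the mean covariance of equal less that of unequal replicate numbers, divided by the number of pairs. The 2 controls cannot be split into parts of at least 2. The replicate numbers of the labels were checked for pairing by correlating, across genes, each library's deviations from its group mean. Between the hlh-2 RNAi and lin-32 RNAi libraries the correlations of equal numbers were 0.265, 0.194 and 0.191, and those of unequal numbers were lower. Deviations from a group mean sum to 0, so positive values for equal numbers push the others down, and the gap is not separate evidence. On the correlations of equal numbers alone, these numbers were taken to pair the 6 libraries. That pairing comes from the data, and the labels give no shared day or batch. For the comparison of these 6 libraries the blocked value is printed where it changes a call or moves a count by over 1.5 times.

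The steps were tested on simulated counts with the real means, dispersions and library sizes and 200 genes changed per treatment. For hlh-2 RNAi against L4440, over 14103 genes, 56.1% of genes changed by 0.5 (log2), 78.8% of those changed by 1 and 92.3% of those changed by 2 were recovered, with 16 false calls among 165. For lin-32 RNAi against L4440 the shares were 54.5%, 81.8% and 92.3%, with 8 false calls among 158. For hlh-2 RNAi against lin-32 RNAi they were 60.6%, 88.6% and 98.5%, with 27 false calls among 352. In these draws the share of false calls was 9.70%, 5.06% and 7.67% in this order, above the nominal threshold in each. In a list test simulated for hlh-2 RNAi against L4440, over 14088 genes, 3 of 3 lists shifted by 0.3 were found and none of the other 30 was called; genes were simulated as independent, so this does not test the correlation setting.

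Alternatives were DESeq2 1.42.0 size factors and its Wald test, library size alone, no filter, a filter of 1 CPM in 3 libraries, limma-voom (limma 3.58.1), only the compared groups in the fit, the replicate number as a block, and leaving out each library in turn. Where a left-out library leaves L4440 with 1 library, that library is assumed to vary like the other groups. No library and no column was left out of the fit with all 8 libraries.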

Results

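Whole nematodes of N2, the standard wild-type strain of Caenorhabditis elegans, were fed bacteria that make double-stranded RNA against 1 of 2 transcription factor genes. LIN-32 is a proneural basic helix-loop-helix (bHLH) protein related to Atonal. HLH-2 is the worm's E protein, the common dimer partner of such bHLH proteins. Controls were fed L4440, the feeding plasmid with no insert. The question, as the series title states it, was how impairing each factor alters expression across the genome. There were 2 L4440, 3 hlh-2 RNAi and 3 lin-32 RNAi libraries, and the stage of the animals is not given in the sources used here. Total counts were 22380739 and 27737470 in the L4440 libraries, 29783012, 33317295 and 32605048 in the hlh-2 RNAi libraries, and 28979768, 34814808 and 30439740 in the lin-32 RNAi libraries. After filtering, 14272 genes were tested.

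The targeted transcripts were examined first, and hlh-2 did not follow its label. The hlh-2 transcript (WBGene00001949, chromosome I, 7190788 to 7193920, minus strand, WBcel235, protein coding) did not differ from the control in the libraries labelled hlh-2 RNAi. It stood at 50.6 ± 2.87 CPM (SD, n = 3) there and at 49.8 ± 1.16 CPM (SD, n = 2) in L4440. The log2 fold change was 0.025 ± 0.15 (SE), with an edgeR adjusted p of 0.990. In the libraries labelled lin-32 RNAi hlh-2 fell to 22.1 ± 6.16 CPM (SD, n = 3), a log2 fold change of -1.16 ± 0.15 (SE, edgeR adjusted p = 0.0041). All 3 of these libraries, at 23, 27.8 and 15.6 CPM, lay below both controls. Without L4440 replicate 2 that fall lost its call (-1.19, edgeR adjusted p = 0.068). Apart from the fit without a filter, its adjusted p over the alternatives ran from 2.1e-04 with DESeq2 to that value. The lin-32 transcript (WBGene00003018, chromosome X, 2229055 to 2230122, minus strand, protein coding) was scarce, with 23 to 114 counts per library. Against 1.46 ± 0.057 CPM in L4440 (SD, n = 2), lin-32 had 2.62 ± 0.69 CPM in the libraries labelled hlh-2 RNAi (SD, n = 3) and 0.81 ± 0.15 CPM in those labelled lin-32 RNAi (SD, n = 3). Neither difference passed the test, with log2 fold changes of 0.85 ± 0.25 (SE, edgeR adjusted p = 0.456) and -0.86 ± 0.29 (SE, edgeR adjusted p = 0.233). Between the 2 RNAi groups both transcripts were higher in the libraries labelled hlh-2 RNAi. The log2 difference was 1.19 ± 0.14 for hlh-2 (SE, edgeR adjusted p = 0.0017) and 1.71 ± 0.23 for lin-32 (SE, edgeR adjusted p = 0.0067). Without the lin-32 RNAi library of replicate 2 the latter was 1.59 (edgeR adjusted p = 0.053), and over the alternatives other than the fit without a filter its adjusted p ran from 1.8e-05 to 0.053. Reads from ingested double-stranded RNA, if captured, would count toward the targeted gene. Groups are therefore named below by their labels, and every direction is drawn between libraries so labelled.

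**Figure D1:**
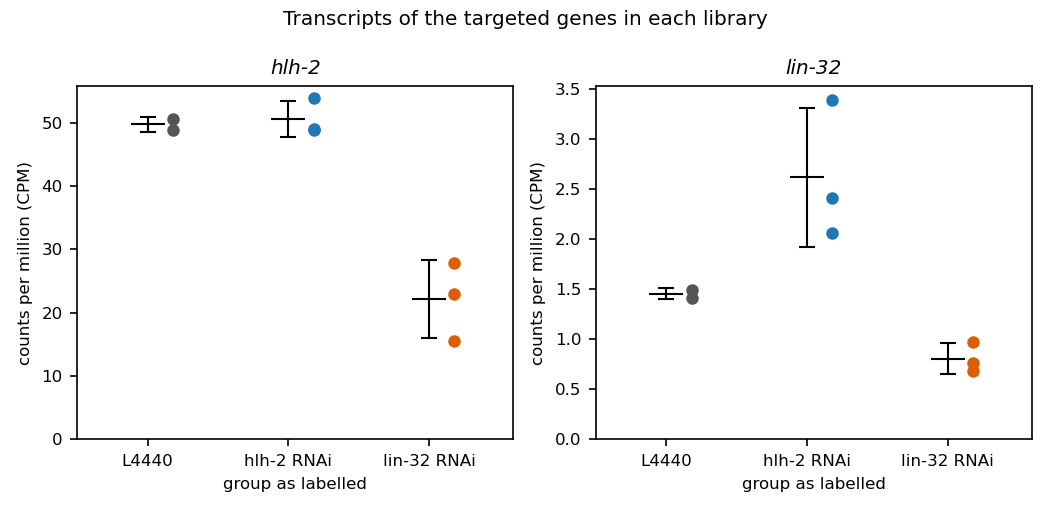
CPM of hlh-2 (left) and lin-32 (right) in each library, by labelled group on the horizontal axis, with points for libraries and bars for the mean ± SD of 2 L4440, 3 hlh-2 RNAi and 3 lin-32 RNAi libraries. The hlh-2 values of the libraries labelled lin-32 RNAi, 15.6 to 27.8 CPM, lie below all others.

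The libraries labelled hlh-2 RNAi differed from L4440 in few genes, and most changes were small. The lysozyme gene lys-7, an immune effector, was the most raised, from 106 ± 22.7 (SD, n = 2) to 263 ± 63 CPM (SD, n = 3), 2.49-fold (edgeR adjusted p = 0.016). The cathepsin B-like protease genes cpr-4 and cpr-1, the UDP-glucuronosyltransferase genes ugt-63 and ugt-32, the lysozyme gene lys-6 and the C-type lectin gene clec-7 also rose, by log2 values of 0.57 to 0.94. The arginine kinase gene argk-1 fell with the smallest p, from 70.3 ± 2.3 (SD, n = 2) to 38.7 ± 0.83 CPM (SD, n = 3), a log2 fold change of -0.86 ± 0.058 (SE, edgeR adjusted p = 4.1e-05). The aspartyl protease gene asp-14 fell by 0.76 on the log2 scale. The uncharacterised F48E3.2, F21C10.9 and C17H12.6 and Y39B6A.21, annotated as a pseudogene, fell by 0.78 to 0.91. The cysteine synthase-like gene cysl-2 fell by 0.36 ± 0.037 (log2, SE, edgeR adjusted p = 0.0015) and the cystathionine gamma-lyase gene cth-1 by 0.40 ± 0.054 (log2, SE, edgeR adjusted p = 0.013).

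In all, 29 of 14272 genes passed the test between the libraries labelled hlh-2 RNAi and L4440, 7 higher and 22 lower, and 3 of them changed over 2-fold. At an unadjusted p under 0.05 there were 968. In all 29 the libraries of the 2 groups did not overlap. The 29 were picked by a test on these same libraries, so this is no separate evidence. Of all tested genes 24.1% showed no overlap, where chance gives 20% for 3 against 2. A pair of IDs named clec-209 fell by 0.49 and 0.48 (log2) and are uncertain, since near-identical copies can share reads. F48E3.2, F21C10.9 and cysl-2 overlap a gene on the other strand, gly-12, F21C10.10 and vnut-1, from which an unstranded library cannot tell them apart. The count was 5 without L4440 replicate 1 and 3 without L4440 replicate 2, and 15 or 13 without replicate 2 or 3 of hlh-2 RNAi. It was 47 with DESeq2. Of the called genes named for this comparison, gst-13 among them, argk-1 and both clec-209 IDs passed with any 1 library left out. The others lost the call without L4440 replicate 2 (edgeR adjusted p from 0.094 to 0.505) and, except cysl-2, without L4440 replicate 1 (0.064 to 0.527). Without replicate 2 of hlh-2 RNAi F21C10.9, Y39B6A.21, clec-7, cth-1, gst-13, lys-6 and ugt-32 lost it too, and without replicate 3 C17H12.6, F21C10.9, Y39B6A.21, cpr-1, gst-13, lys-6 and ugt-32. The lys-6 call was lost without any of the 8 libraries and that of ugt-32 without any except replicate 1 of lin-32 RNAi. For C17H12.6 it was lost also without replicate 1 of hlh-2 RNAi or replicate 3 of lin-32 RNAi, and for gst-13 without the latter. Among the other settings, lys-6 did not pass with library size alone, a filter of 1 CPM, limma-voom or only the 2 groups compared (adjusted p from 0.051 to 0.125). Nor did C17H12.6 with library size alone or a filter of 1 CPM (edgeR adjusted p = 0.057 and 0.051), gst-13 with library size alone (edgeR adjusted p = 0.104), or ugt-32 with only the 2 groups compared (edgeR adjusted p = 0.103).

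Of the 33 lists, 8 passed the camera test in this comparison, all toward lower values, and none passed with an estimated correlation or with fry. Ribosomal protein genes had 1 of 78 members above 0 and a median log2 fold change of -0.095 (camera adjusted p = 2.0e-21), yet adjusted p = 0.28 with an estimated correlation. None of these members passed alone over all genes, and 3 fell adjusted over the list alone; the lowest p belonged to rpl-31 at -0.18 and rpl-35 at -0.15. Cuticle collagen genes had a median of -0.12 over 105 members, none past the test in either count (camera adjusted p = 4.5e-07, and adjusted p = 0.44 with an estimated correlation). Examples were col-90, which overlaps let-754 on the other strand, at -1.61 ± 0.35 and col-93, which overlaps dhc-4, at -0.43 ± 0.11 (log2, SE). Glutathione S-transferase genes had a median of -0.16 over 35 members (camera adjusted p = 1.1e-04, and adjusted p = 0.28 with an estimated correlation). Of these gst-13 fell by 0.36 (log2), and 2 fell adjusted over the list alone. Nuclear respiratory chain genes had a median of -0.052 over 43 members (camera adjusted p = 1.1e-04, and adjusted p = 0.63 with an estimated correlation), with asb-2 at -0.12 and atp-4, which overlaps T05H4.11, at -0.11. Among 103 C-type lectin genes 1 rose and 5 fell, and 2 rose and 8 fell adjusted over the list alone. Their median was -0.045 while their mean was 7.1e-04, so median and mean differ in sign (camera adjusted p = 0.030, and adjusted p = 0.28 with an estimated correlation). The medians of the remaining lists that passed were -0.083 for 6 vitellogenin genes, which encode yolk proteins, -0.034 for 31 oocyte and eggshell genes and -0.035 for 39 germline and meiosis genes. No member of these lists passed, alone or over the list alone. Their camera adjusted p-values were 0.020, 0.020 and 0.050, and with an estimated correlation the adjusted p-values were 0.63, 0.65 and 0.63.

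Where no member of a list passed over all genes, members at an unadjusted p under 0.05 numbered 36 of the ribosomal protein, 10 of the collagen, 6 of the respiratory chain, 3 of the germline, 1 of the oocyte and 1 of the vitellogenin genes. DESeq2 called 4 ribosomal protein genes and 0 in the other 5 of these lists, and limma-voom called 0 in all 6. The ribosomal and respiratory chain lists passed camera with any 1 library left out. Without L4440 replicate 1 the collagen, C-type lectin, germline, oocyte and vitellogenin lists did not pass (camera adjusted p from 0.086 to 0.808). Without L4440 replicate 2 the glutathione S-transferase, C-type lectin, germline and vitellogenin lists did not (0.054 to 0.407). The oocyte and vitellogenin calls were lost without replicate 1 of hlh-2 RNAi. The C-type lectin, germline and vitellogenin calls were lost without replicate 2, the C-type lectin and germline calls without replicate 3, and the germline call also without replicate 3 of lin-32 RNAi. With library size alone the oocyte and germline lists did not pass (camera adjusted p = 0.15 and 0.30), nor did the germline list with DESeq2 size factors (camera adjusted p = 0.059).

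The libraries labelled lin-32 RNAi differed from L4440 in 106 genes, and the lower ones included egl-46, fmi-1 and the cuticle collagen genes sqt-1 and col-17. The zinc finger gene egl-46, which acts in neuronal differentiation, fell from 6.98 ± 1.81 (SD, n = 2) to 1.18 ± 0.17 CPM (SD, n = 3), a log2 fold change of -2.54 ± 0.20 (SE, edgeR adjusted p = 1.1e-04). The flamingo cadherin gene fmi-1, which guides axons, fell by 1.47 ± 0.15 (log2, SE, edgeR adjusted p = 6.6e-04), the arrestin domain gene arrd-1 by 1.91 ± 0.18 (log2, SE, edgeR adjusted p = 6.3e-04) and syd-9, a zinc finger gene of synapse function, by 0.95 ± 0.14 (log2, SE, edgeR adjusted p = 0.0091). The collagen genes sqt-1 and col-17 rested on few counts. The sqt-1 gene had 25 and 42 counts in the L4440 libraries and 4, 1 and 0 in those labelled lin-32 RNAi, and col-17 had 42 and 55 against 7, 5 and 2. As in the libraries labelled hlh-2 RNAi, argk-1 was lower, 2.14-fold (edgeR adjusted p = 2.7e-06), and F21C10.9 fell by 1.07.

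Among raised genes were lys-7, 2.06-fold (edgeR adjusted p = 0.025), and cpr-4, 1.82-fold (edgeR adjusted p = 9.4e-04). The UDP-glucuronosyltransferase genes ugt-63, ugt-32 and ugt-25 rose by log2 values of 0.94, 0.81 and 0.62. The Sec61 translocon subunit gene sec-61.B rose 1.91-fold, a log2 fold change of 0.93 ± 0.10 (SE, edgeR adjusted p = 0.0010). The S-adenosylmethionine decarboxylase gene smd-1, of polyamine synthesis, and cpr-1 rose by 0.40 and 0.56 and ZK1290.5 by 0.96. Here ugt-25 overlaps mlst-8 on the other strand.

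Altogether 106 genes passed between the libraries labelled lin-32 RNAi and L4440, 30 higher and 76 lower. Of the 47 that changed over 2-fold, 43 were lower. At an unadjusted p under 0.05 there were 1797. The libraries of the groups did not overlap in any of the 106, which is no separate evidence, since the test picked them on these libraries. No overlap was seen in 29.8% of all tested genes, where chance gives 20%. Without L4440 replicate 1 the count was 41 and without L4440 replicate 2 it was 17. It was 67 without replicate 2 of hlh-2 RNAi, 60 or 61 without replicate 2 or 3 of lin-32 RNAi, 64 with a filter of 1 CPM and 178 with DESeq2. Of the called genes named for this comparison here and among its lists and shared genes, ZK1290.5, cpr-1, cyp-25A2, lys-6, lys-7, rol-6 and syd-9 lost the call without L4440 replicate 1 (edgeR adjusted p from 0.067 to 0.266). Those that lost it without L4440 replicate 2 were ZK1290.5, col-90, cpr-1, cyp-25A2, cysl-2, lys-6, lys-7, rla-1, rol-6, smd-1, ugt-25, ugt-32 and hlh-2 (0.066 to 0.282). The calls of cyp-25A2, lys-6 and lys-7 were lost also without replicate 2 of hlh-2 RNAi (0.053 to 0.071), and those of lys-6 and lys-7 without replicate 1 of lin-32 RNAi (0.073 and 0.060). Without replicate 2 of lin-32 RNAi cyp-25A2, lys-6, lys-7, rla-1 and rol-6 did not pass (0.058 to 0.089), and without replicate 3 cyp-25A2 and lys-6 did not (0.057 and 0.096). Nor did cyp-25A2 and lys-6 with limma-voom (adjusted p = 0.059 each), or cyp-25A2 with a filter of 1 CPM (edgeR adjusted p = 0.054). The others, egl-46, fmi-1, arrd-1, sqt-1, col-17, argk-1, F21C10.9, cpr-4, ugt-63, sec-61.B and cth-1, passed with any 1 library left out.

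**Figure D2:**
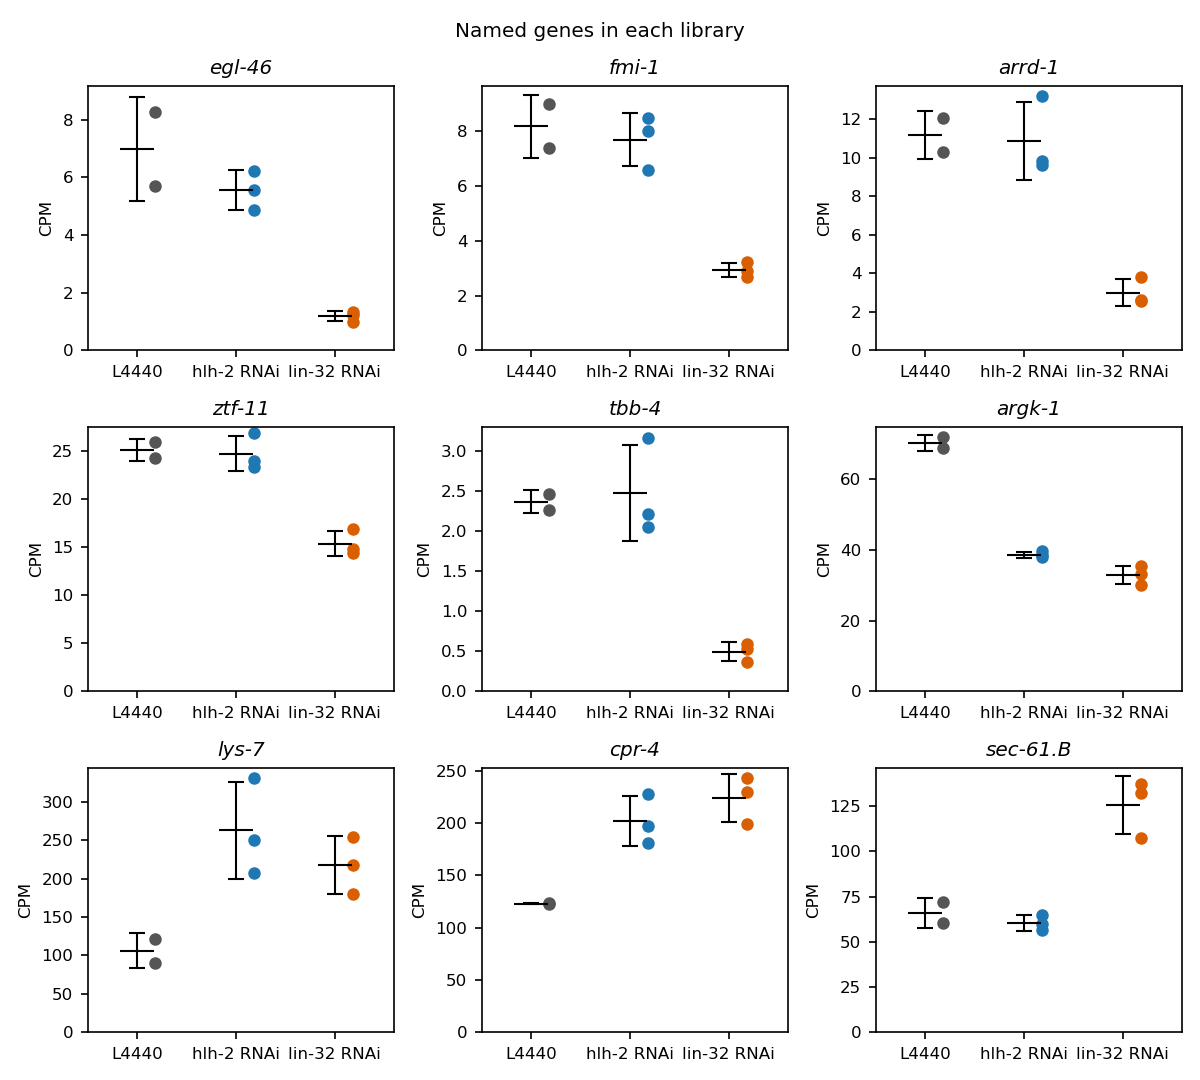
CPM of 9 genes in each library, by labelled group, with points for libraries and bars for the mean ± SD of 2, 3 and 3 libraries. In egl-46, fmi-1, arrd-1, ztf-11 and tbb-4 the libraries labelled lin-32 RNAi lie below all others, whereas argk-1, lys-7 and cpr-4 part both RNAi groups from L4440.

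In this comparison 8 of 33 lists passed camera, 3 toward higher and 5 toward lower values. None passed with an estimated correlation, and fry called 3. Genes of the sensory cilium had a median log2 fold change of -0.42, and 3 of 43 members lay above 0 (camera adjusted p = 1.8e-07, adjusted p = 0.093 with an estimated correlation, and 0.010 with fry). No cilium gene passed alone with edgeR, DESeq2 or limma-voom, 14 had an unadjusted p under 0.05, and 6 fell adjusted over the list alone. The lowest p belonged to the transition zone gene nphp-1 at -1.53 ± 0.37 and to dyf-7 at -0.96 ± 0.26 (log2, SE). The bHLH list, which holds both targeted genes, had a median of -0.45 over 8 members, of which hlh-2 fell, and 2 fell adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.34 with an estimated correlation). Its other low members were cnd-1 at -0.56 ± 0.28 and ngn-1 at -0.50 ± 0.27 (log2, SE). Of 105 collagen genes 9 fell and 1 rose, and 16 fell and 6 rose adjusted over the list alone. Their median was -0.029 and their mean -0.42 (camera adjusted p = 0.0018, and adjusted p = 0.71 with an estimated correlation). Without L4440 replicate 1 the collagen list turned toward higher values (camera adjusted p = 0.959), and over its alternatives the adjusted p ran from 3.1e-11 to that value. The collagens that fell included col-90 at -3.09 ± 0.43 and rol-6 at -3.75 ± 0.59 (log2, SE), both from few counts. UDP-glucuronosyltransferase genes had a median of 0.11 over 58 members, with 3 higher, or 5 adjusted over the list alone (camera adjusted p = 3.0e-04, adjusted p = 0.093 with an estimated correlation, and 0.010 with fry). Cytochrome P450 genes had a median of 0.14 over 61 members, of which cyp-25A2 rose by 0.39, also when adjusted over the list alone (camera adjusted p = 0.0045, adjusted p = 0.10 with an estimated correlation, and 0.010 with fry).

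Intestine genes had a median of 0.035 over 27 members, where cpr-4 and cpr-1 rose, and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0043, and adjusted p = 0.68 with an estimated correlation). Ribosomal protein genes had a median of -0.048, although rla-1 rose by 0.63 ± 0.11 (log2, SE), alone and over the list alone (camera adjusted p = 0.0043, and adjusted p = 0.74 with an estimated correlation). Embryonic cell fate genes had a median of -0.096 over 32 members, with ceh-43 at -0.72 ± 0.17 (log2, SE), and passed camera (camera adjusted p = 0.0043, and adjusted p = 0.68 with an estimated correlation). None of them passed the edgeR test alone and 3 fell adjusted over the list alone, 7 had an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 0. Pan-neuronal genes, the synaptic genes that neurons share, gave a median of 0.021 and a mean of -0.033 over 27 members, with the test toward lower values, so the signs differ, and did not pass (camera adjusted p = 0.90). Touch receptor neuron genes gave -0.069 over 15 members and did not pass either (camera adjusted p = 0.38), with the POU homeobox gene unc-86 at -0.74 ± 0.24 (log2, SE). The cilium and UDP-glucuronosyltransferase lists passed with any 1 library left out. Without L4440 replicate 1 the bHLH, cytochrome P450, ribosomal, embryonic and collagen lists did not pass (camera adjusted p from 0.052 to 0.959). The embryonic list did not pass without replicate 1 of lin-32 RNAi (0.059), nor the intestine list without L4440 replicate 2 (0.051) or replicate 3 of lin-32 RNAi (0.10).

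The direct comparison of the 2 RNAi groups parted egl-46, arrd-1 and fmi-1 too. In the libraries labelled hlh-2 RNAi egl-46 was 4.68-fold higher, at 5.56 ± 0.68 against 1.18 ± 0.17 CPM (SD, n = 3 each). Likewise arrd-1 was 3.64-fold, fmi-1 2.62-fold and the beta-tubulin gene tbb-4, which ciliated neurons use, 5.03-fold higher. The Snail-type repressor gene ces-1 differed by 3.53 ± 0.37 (log2, SE, edgeR adjusted p = 8.2e-04), from 1 to 3 counts in each library labelled lin-32 RNAi, and overlaps cpn-1 on the other strand. Further genes higher in the libraries labelled hlh-2 RNAi were the zinc finger gene ztf-11 at 0.69 ± 0.075, syd-9 at 0.84 ± 0.13 and ced-11 at 0.82 ± 0.14 (log2, SE). Lower in these libraries were sec-61.B, by 1.06 ± 0.087 (log2, SE, edgeR adjusted p = 2.3e-04), and the ribosomal stalk gene rla-1, at 558 ± 65.9 against 942 ± 46.7 CPM (SD, n = 3 each). Y82E9BR.3 was lower by a log2 value of -0.68, mai-2, an ATP synthase inhibitor gene, by -0.75, and the collagen genes col-93, col-42 and col-122 by -0.67, -0.60 and -0.39. The microtubule end-binding gene ebp-2 and a clec-209 copy each differed by -0.23. On the other strand rla-1 overlaps arl-13, Y82E9BR.3 overlaps lelo-2, col-93 overlaps dhc-4 and col-122 overlaps lron-14.

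In total 58 genes differed between the 2 RNAi groups, 42 higher and 16 lower in the libraries labelled hlh-2 RNAi, with 34 over 2-fold. At an unadjusted p under 0.05 there were 1137. None of the 58 had overlapping groups, again no separate evidence because the test picked them on these libraries. Groups did not overlap in 13.7% of all tested genes, where chance gives 10% for 3 against 3. The numbers were taken from these data to pair the 6 libraries. With the replicate number as a block, 132 genes passed in the fit of all 8 libraries, and all 58 were among them. In 10 simulated unchanged data sets, which held no pairing, the blocked fit called 2 to 6 genes in this comparison, against 0 to 4 without the block. The block fitted on these 6 libraries alone, an alternative chosen after seeing the data, gave 386 genes, again with all 58, against 57 in those 6 libraries without it. The count was 93 or 28 or 31 without replicate 1, 2 or 3 of hlh-2 RNAi, 25 without replicate 2 of lin-32 RNAi and 91 with DESeq2. Without replicate 2 of lin-32 RNAi the named genes Y82E9BR.3, ced-11, col-42, ebp-2, lin-32, mai-2 and syd-9 did not pass (edgeR adjusted p from 0.053 to 0.187). Without replicate 2 of hlh-2 RNAi ced-11, col-122, col-42 and syd-9 did not (0.060 to 0.075), and without replicate 3 ced-11, col-122, col-42, ebp-2 and mai-2 did not (0.055 to 0.131). Without replicate 3 of lin-32 RNAi ced-11, col-122 and col-42 did not (0.055 to 0.121), and col-42 was lost also without replicate 1 (0.070), with DESeq2 (0.067) and with a filter of 1 CPM (0.069). The other genes named above from the 58 passed with any 1 library left out.

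Of the 33 lists, 9 passed camera between the 2 RNAi groups, 4 toward higher and 5 toward lower values in the libraries labelled hlh-2 RNAi. Counts of members past the test are without the replicate block unless it is named. Cilium genes had a median difference of 0.31, with 37 of 43 members above 0 (camera adjusted p = 4.8e-09, adjusted p = 0.12 with an estimated correlation, and 0.041 with fry). With the replicate block osm-5 passed (1.47, edgeR adjusted p = 0.048), while without it no member passed alone and 5 were higher adjusted over the list alone, with daf-10, which overlaps flp-1 on the other strand, at 1.19 ± 0.27 and osm-5 at 1.46 ± 0.37 (log2, SE). The bHLH list had a median of 0.30, and both of its members past the test, alone and over the list alone, were the targeted genes (camera adjusted p = 1.3e-07, and adjusted p = 0.12 with an estimated correlation). Embryonic cell fate genes had a median of 0.13, none past the test alone and 4 higher adjusted over the list alone (camera adjusted p = 5.9e-05, and adjusted p = 0.29 with an estimated correlation), with sdz-28 at 0.43 and vet-6 at 0.26. Somatic gonad genes had a median of 0.029 over 21 members, none past the test alone and 3 higher over the list alone, with lag-2, a Notch ligand gene, at 0.91 ± 0.25 (camera adjusted p = 0.047, and adjusted p = 0.29 with an estimated correlation).

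Toward lower values in the libraries labelled hlh-2 RNAi, ribosomal protein genes had a median of -0.047, of which rla-1 passed in both counts (camera adjusted p = 9.2e-08, and adjusted p = 0.44 with an estimated correlation). Nuclear respiratory chain genes had a median of -0.035, none past the test alone and 3 adjusted over the list alone, with cox-5A at -0.32 ± 0.068 (camera adjusted p = 2.9e-04, and adjusted p = 0.44 with an estimated correlation). All 12 mitochondrial genome genes lay below 0, with a median of -0.10 and no member past the test in either count (camera adjusted p = 6.3e-04, and adjusted p = 0.31 with an estimated correlation). UDP-glucuronosyltransferase genes had a median of -0.082, with none past the test alone and 1 over the list alone (camera adjusted p = 0.0075, adjusted p = 0.12 with an estimated correlation, and 0.041 with fry). Lysozyme and antimicrobial peptide genes had a median of -0.067 over 70 members, none past the test in either count (camera adjusted p = 0.0075, and adjusted p = 0.33 with an estimated correlation). With the replicate block the cytochrome P450 and intestine lists passed too, toward lower values (camera adjusted p = 0.026 and 0.028), against 0.11 and 0.058 without it. With an estimated correlation and no block their camera adjusted p-values were 0.29 and 0.55. Of 105 collagen genes 3 were higher and 3 lower, or 14 and 16 adjusted over the list alone. Their median was -0.053 and their mean 0.22, so the signs differ, and the test, toward lower values, did not pass (camera adjusted p = 0.57).

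With the replicate block more members passed alone: 1 of the cilium list (osm-5), 1 of the embryonic, 2 of the respiratory chain, 1 of the mitochondrial genome, 1 of the UDP-glucuronosyltransferase, 1 of the lysozyme and 2 of the ribosomal list, and 13 collagen genes against 6 without it. They included vet-6 at 0.26 (edgeR adjusted p = 0.038), cox-5A at -0.33 (edgeR adjusted p = 0.029), cox-6C at -0.16 (edgeR adjusted p = 0.028), rla-2 at -0.21 (edgeR adjusted p = 0.029) and MTCE.12, which overlaps ND1, at -0.58 (edgeR adjusted p = 0.047). The UDP-glucuronosyltransferase gene was ugt-22, which overlaps srz-29 on the other strand, at -0.17 (edgeR adjusted p = 0.030). The lysozyme gene was lys-7, which stood against its list's direction at 0.26 (edgeR adjusted p = 0.0092, against 0.734 without the block). In lists that did not pass or passed only with the block, further members passed with it, chosen for naming after their values were seen. They were lys-7 and tts-1 (-0.16) of the DAF-16 list, cyp-35A2 (-0.25) and cyp-35C1 (-0.26) of the cytochrome P450 list, acs-2 (-0.29) and lbp-1 (0.28) of the lipid metabolism list, and flp-14 (-0.52) of the FMRFamide-like peptide list. The histone gene his-24, which overlaps noncoding RNA genes on the other strand, stood at 0.24 and cav-1 of the oocyte list at 0.29 (edgeR adjusted p from 0.0064 to 0.048 for all of these).

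Where no member passed over all genes with edgeR and no block, those at an unadjusted p under 0.05 numbered 11 of the cilium, 6 of the embryonic, 3 of the somatic gonad, 9 of the respiratory chain, 3 of the mitochondrial genome, 7 of the UDP-glucuronosyltransferase and 4 of the lysozyme list. DESeq2 called 1 embryonic gene and 0 in the other 6 lists, and limma-voom 0 in all 7. The cilium, bHLH, embryonic and ribosomal lists passed camera with any 1 library left out. The respiratory chain list did not pass without replicate 1 of hlh-2 RNAi (camera adjusted p = 0.077), nor the mitochondrial genome list without replicate 3 of lin-32 RNAi (0.076). The UDP-glucuronosyltransferase, lysozyme and somatic gonad lists did not without replicate 2 of hlh-2 RNAi (0.064 to 0.153). The last of these did not without replicate 1 of lin-32 RNAi (0.056), and the lysozyme and somatic gonad lists did not without replicate 2 of lin-32 RNAi (0.123 to 0.134). In none of the 3 comparisons did the other 16 lists pass. These were the genes of touch receptor neurons, of pan-neuronal function, of dopamine and serotonin, of FMRFamide-like peptides, of antioxidant defence, of mitochondrial, endoplasmic reticulum and heat stress, of DAF-16 induction, of moulting, sperm, muscle, lipid metabolism and the proteasome, of histones and of RNA interference. Their lowest camera adjusted p was 0.052, for FMRFamide-like peptides in lin-32 RNAi against L4440, and the next was 0.11.

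**Figure D3:**
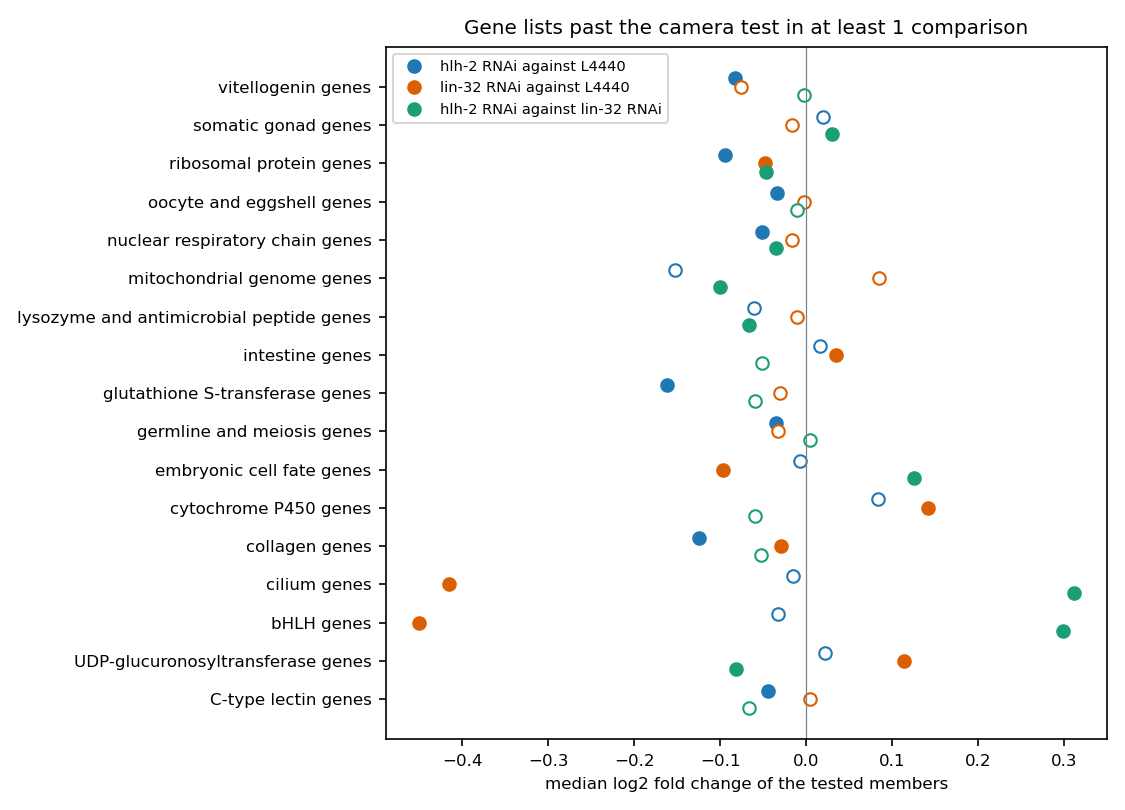
Median log2 fold change of the tested members of each list that passed camera in at least 1 of 3 comparisons, coloured by comparison, with filled points where it passed (adjusted p under 0.05 with the preset correlation) and open points where it did not. Cilium and bHLH genes lie farthest from 0, at -0.42 and -0.45 for lin-32 RNAi against L4440.

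The 2 comparisons with L4440 shared 23 called genes, all changed in the same direction, 6 higher and 17 lower. The shared genes included argk-1, cysl-2, cth-1, lys-7, lys-6, cpr-4, cpr-1, ugt-63 and ugt-32. Lists drawn independently would share 0.015 higher and 0.12 lower genes, a figure that leaves out the shared L4440 libraries. Simulated unchanged groups, each pair set against the same 2 simulated controls, shared 0 to 2. Few genes are called in unchanged data, 0 to 4 per comparison with the filtered fit in 10 simulated sets. Few could therefore be shared there, and neither figure is a benchmark for the 23. Across all 14272 genes, which are not independent replicates, the covariance of the log2 fold changes was 0.0451 and the simulated one averaged 0.0344, with a highest value of 0.0375. The correlation was 0.59, below every simulated draw, which ran from 0.62 to 0.67 with a mean of 0.65. Signs were alike in 74.2% of genes and in 71.5% on average in the simulation. The simulation left out the pairing of equal replicate numbers between the RNAi groups, which was estimated to add 0.00456 to the covariance. The controls could not be split, so part of the excess may come from the shared L4440 libraries. Of the 23 genes, 2 also differed between the 2 RNAi groups, both named clec-209, and with the replicate block 3 did, lys-7 being the other. The overlap was 5 without L4440 replicate 1 and 1 without L4440 replicate 2. It was 12 or 11 without replicate 2 or 3 of hlh-2 RNAi, 14 without replicate 3 of lin-32 RNAi and 35 with DESeq2.

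**Figure D4:**
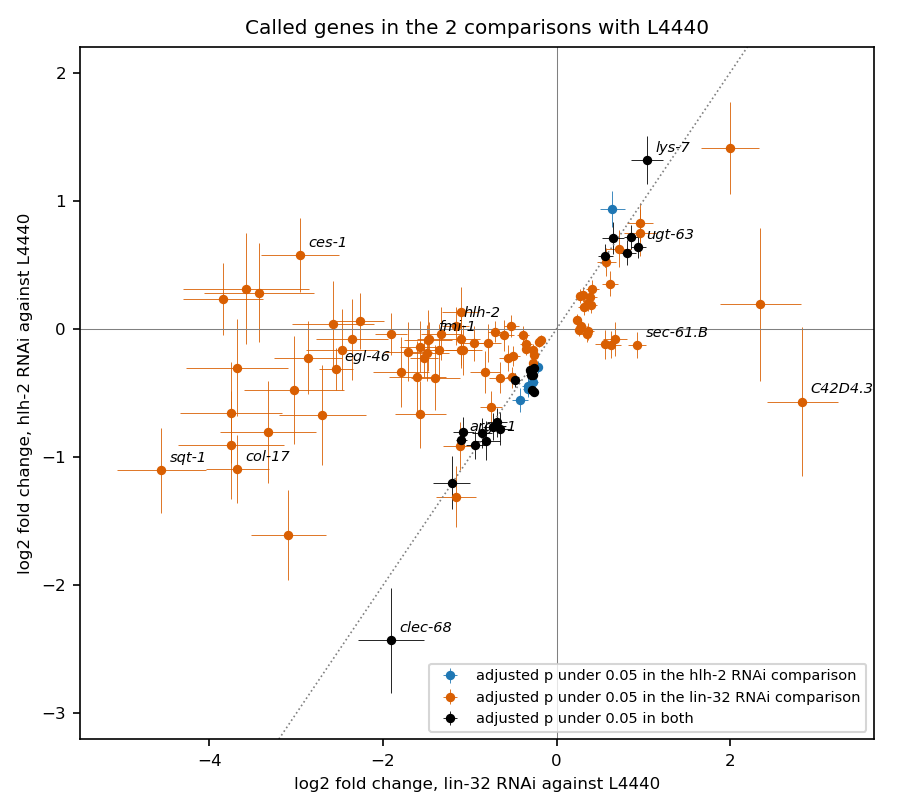
Log2 fold change against L4440 in the libraries labelled lin-32 RNAi (horizontal) and hlh-2 RNAi (vertical) for each gene past the test in either, with SE bars and a dotted line of equal change. The 23 genes called in both, in black, lie near that line, while egl-46 and sqt-1 lie far to its left.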

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

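The tests that weigh explanations in this part were chosen after the results they bear on were seen, and the count over other splits of the libraries was chosen before.

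The 3 results here stood out because the 2 RNAi groups differed in a direct test. The hlh-2 transcript was 1.19 (log2) higher in the libraries labelled hlh-2 RNAi than in those labelled lin-32 RNAi, and lin-32 was 1.71 higher. For hlh-2 this order is opposite to the one knockdown as labelled would give, and for lin-32 it is that order. The third result is the count of 58 genes that differed. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached. Among the 4 splits that part all 3 pairs the others also gave 0, and with the replicate block the real split gave 132 and the highest of the others 2.

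The fall of hlh-2 in the libraries labelled lin-32 RNAi, and its level near L4440 in those labelled hlh-2 RNAi, was weighed first. If the labels of the 2 RNAi groups were exchanged and counts reported knockdown alone, lin-32 would lie below L4440 in the libraries labelled hlh-2 RNAi, yet it lay above by 0.85 ± 0.25 (log2, SE), in all 3 libraries, although this did not pass the test (edgeR adjusted p = 0.456). Exchanged labels with reads from ingested double-stranded RNA cannot be told apart from right labels with such reads, because gene totals carry no coverage along the gene. The former needs such reads to outweigh knockdown for lin-32, at 0.85, and not for hlh-2, at -1.16. The latter needs them to make up for knockdown of hlh-2, at 0.025. In the libraries labelled lin-32 RNAi the former leaves the lin-32 value of -0.86 (edgeR adjusted p = 0.233) to another cause, and the latter the hlh-2 fall. A lower hlh-2 level that follows from lin-32 RNAi itself is a biological explanation and stays open, untested. Right labels with an hlh-2 RNAi that did not lower its transcript stay open too. The counts alone show no fall of hlh-2 in those libraries, at 0.025 ± 0.15 (log2, SE).

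The second pattern is the lower level of 9 cuticle collagen genes in the libraries labelled lin-32 RNAi, with log2 fold changes from -4.55 to -1.40. All 9 also lay below L4440 in the libraries labelled hlh-2 RNAi, at -1.61 to -0.38, where none passed the test. This is no separate evidence, because the 9 were picked against the same controls. Of the 76 genes called lower in the libraries labelled lin-32 RNAi, 88.2% lay below L4440 in those labelled hlh-2 RNAi. In simulated unchanged sets 90.8% to 100% of the 76 lower genes with the smallest p did so. Between the RNAi groups 3 of the 9 differed, col-17, sqt-1 and rol-6 (edgeR adjusted p = 0.0097, 0.014 and 0.040), and with the replicate block dpy-5 and sqt-2 did too (edgeR adjusted p = 0.029 each), but without replicate 2 of lin-32 RNAi none of the first 3 passed (0.070, 0.109 and 0.210), sqt-1 did not without replicate 2 of hlh-2 RNAi (0.060), and rol-6 passed only with all libraries or without replicate 1 of lin-32 RNAi among the fits that left 1 out. Fewer embryos and larvae of every stage would lower the embryonic cell fate genes too, whose median was -0.096 and lower quartile -0.28. The 9 collagens were picked for their fall and the 32 embryonic genes were not, so this comparison cannot decide. The whole collagen list had a median of -0.029. The embryonic list itself passed camera toward lower values (camera adjusted p = 0.0043, and adjusted p = 0.68 with an estimated correlation). A lower depth is argued against, since the smallest total of these libraries was 1.04 times the largest L4440 total. Fewer animals of 1 late stage cannot be told apart from an effect of the RNAi, since no list of such a stage was fixed, and the median of 8 cuticle genes known for earlier expression, -0.17, does not bear on it. An effect of the RNAi on the cuticle or on the timing of the animals stays open.

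The third pattern is the 23 genes that changed alike in both RNAi groups. The covariance of the log2 fold changes exceeded the simulated mean by 0.0107, above every simulated draw, and their correlation of 0.59 lay below every draw (0.62 to 0.67). The simulation treats genes as independent and leaves out the pairing of equal replicate numbers, estimated to add 0.00456 to the covariance, and the 2 controls cannot be split, so that pairing and chance values of those controls may account for part of that excess. A difference in handling between the L4440 and the RNAi libraries cannot be told apart from a response common to both treatments, as no library parts them, and 2 of the 23 genes differed between the RNAi groups, or 3 with the replicate block. A common biological response stays open.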

How the results depend on the processing

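The 6-library block and the counts without collagens and targeted genes (95 for lin-32 RNAi against L4440 and 50 for hlh-2 RNAi against lin-32 RNAi) were chosen after seeing the data. No called gene changed sign in any setting. For the named genes other than the targets, 1337 of 1588 values under an alternative kept both direction and side of the threshold, 193 kept the direction and lost the threshold, and 58 kept the direction and gained it. Of named genes that did not pass, rpl-31 and rpl-35 in hlh-2 RNAi against L4440, ast-1, ceh-43 and zag-1 in lin-32 RNAi against L4440 and flp-14 and sdz-28 between the RNAi groups passed with DESeq2 (adjusted p from 0.0042 to 0.039), and cox-5A with only the 2 groups compared (edgeR adjusted p = 0.013). With 1 library left out ast-1, ceh-43, zag-1, sdz-28 and cox-5A passed in the same comparisons (edgeR adjusted p from 0.011 to 0.046). For the lists, 242 of 325 kept both, 82 lost the threshold and 1 reversed. Counts are given for hlh-2 RNAi against L4440 (29), lin-32 RNAi against L4440 (106), hlh-2 RNAi against lin-32 RNAi (58) and the overlap of the 2 RNAi treatments (23), in this order. DESeq2 gave 47, 178, 91 and 35, and shared 28, 95 and 56 genes with the edgeR calls; the cause was not tested. A filter of 1 CPM gave 64 for the second, where 86 of the 106 genes were still tested. No filter gave 223, 610, 342 and 170, but its p-values are not reliable: the fit set an infinite prior for the spread of all 23063 genes, against 7.40 degrees of freedom with the filter, so a gene's own spread was ignored. In 10 simulated unchanged data sets it called 13 to 28, 11 to 30 and 16 to 36 genes, and the filtered fit 0 to 4. The calls of lin-32 gained there, at 0.86 (edgeR adjusted p = 0.017) and -0.86 (edgeR adjusted p = 0.044), carry no weight. Over its other settings the adjusted p of lin-32 ran from 0.146 to 0.902 and from 0.175 to 0.538. The replicate block gave 72, 350, 132 and 63 and a common dispersion of 0.00193 against 0.00270. In the 10 simulated unchanged data sets, which held no pairing, the blocked fit also made false calls. They numbered 0 to 8 for hlh-2 RNAi against L4440, 0 to 6 for lin-32 RNAi against L4440 and 2 to 6 between the RNAi groups. The 6-library fit gave 57 without and 386 with the replicate block. The L4440 numbers do not pair: with hlh-2 RNAi their correlations were -0.066 and -0.16, with lin-32 RNAi -0.037 and -0.12, over 2 pairs. Among the 6 RNAi libraries each correlated best with its own number. In the paired comparison the block ended no call of a named gene or list, and the list members it added are given with the results. In hlh-2 RNAi against L4440, where the numbers do not pair the libraries, the C-type lectin and germline lists did not pass with the block (camera adjusted p = 0.127 and 0.060).

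Leaving out 1 library at a time gave 3 to 31, 17 to 157, 25 to 93 and 1 to 24 genes. A fit with 1 control has less power, and the results also differed by which control was left out. Single controls can differ by chance, so this does not decide whether less power explains the lower counts. The causes, there and for single RNAi libraries, were not tested. The value of hlh-2 in hlh-2 RNAi against L4440 ran from -0.022, without hlh-2 RNAi replicate 3, to 0.050. That of hlh-2 in lin-32 RNAi against L4440 ran from -1.37 to -0.97, with edgeR adjusted p from 4.3e-04 to 0.068. That of lin-32 in hlh-2 RNAi against lin-32 RNAi ran from 1.48 to 1.87, with edgeR adjusted p from 0.0038 to 0.053. Of 25 list calls, 0 held with an estimated correlation and 5 with fry. With 1 library left out 15 to 28 passed, and with the block 29, among them 23 of the 25. The collagen list of lin-32 RNAi against L4440 had camera adjusted p from 3.1e-11 to 0.959, the latter in the other direction; the cause was not tested. Depth limits genes such as sqt-1 and ces-1, which rest on few counts.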

Other observations

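The test of gene families and the choice of genes in this part were made after the values were seen. In the libraries labelled lin-32 RNAi the homeobox gene unc-42, a factor of neuronal identity, fell by 1.48 ± 0.28 (log2, SE, edgeR adjusted p = 0.030) against L4440. Without either L4440 library, replicate 2 of hlh-2 RNAi or replicate 1 or 2 of lin-32 RNAi its log2 fold change was -1.66 to -1.30 and the call was lost (0.058 to 0.235). The ETS gene ast-1, which overlaps rhgf-2 on the other strand, and the zinc finger homeobox gene zag-1 did not pass against L4440, at -1.21 ± 0.26 and -0.97 ± 0.21 (log2, SE, edgeR adjusted p = 0.055 and 0.060), although both did with DESeq2 (adjusted p = 0.039 and 0.018). Between the RNAi groups both did, at 1.30 and 0.99 (edgeR adjusted p = 0.022 and 0.040), higher in the libraries labelled hlh-2 RNAi. The ast-1 call was lost without replicate 2 or 3 of hlh-2 RNAi or any lin-32 RNAi library (0.065 to 0.144). The zag-1 call was lost without any library except replicate 1 of hlh-2 RNAi and replicate 2 of lin-32 RNAi (0.069 to 0.179), and with a filter of 1 CPM, limma-voom or only the 2 groups compared (0.054 to 0.076). The uncharacterised gene C42D4.3 went the other way, with 0.53 ± 0.025 CPM in L4440 (SD, n = 2), 0.35 ± 0.10 in the libraries labelled hlh-2 RNAi (SD, n = 3) and 3.71 ± 1.67 in those labelled lin-32 RNAi (SD, n = 3). Against L4440 C42D4.3 rose by 2.83 (log2, edgeR adjusted p = 0.0068) in the latter. Without L4440 replicate 1 or 2 its log2 fold change was 2.88 or 2.78 and the call was lost (0.095 and 0.135).

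A hypothesis from the list of lowered genes was that adaptor families of ubiquitin ligases (F-box, SKP1-related, BTB and MATH genes) are over-represented in it. Of 333 such genes tested, 7 were among the 76 lower in the libraries labelled lin-32 RNAi, where 1.77 would be drawn by chance. The odds ratio was 4.32 (95% interval 1.66 to 9.47, two-sided Fisher's exact p = 0.0019). They were fbxb-65, fbxb-42, fbxb-83, fbxc-8, btb-8, skr-7 and skr-8, with log2 fold changes from -2.47 to -0.35, and fbxc-8 is 1 of several IDs of that name. All 7 lost the call without L4440 replicate 1 (edgeR adjusted p from 0.051 to 0.252) and without L4440 replicate 2 (0.123 to 0.432), and each lost it without at least 2 of replicates 1, 2 and 3 of lin-32 RNAi and 2 and 3 of hlh-2 RNAi (0.050 to 0.133). With DESeq2 fbxb-83 and fbxc-8 did not pass (adjusted p = 0.083 and 0.10), nor did they with limma-voom or only the 2 groups compared (0.052 to 0.063). With a filter of 1 CPM fbxb-83 and btb-8 did not (0.061 and 0.052), nor did fbxb-83 with library size alone (0.051). Members of such families can share reads and were picked for the test after they were seen, so the p-value overstates the evidence, and the pattern may reflect the choice of families.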
